A study of Mus musculus with 2 samples.

How the data were processed

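Posterior parts of mouse embryos of 13 somites were compared between Cdx2+/-Cdx4-/- mutants and wildtypes. Per the labels' protocols, tissue of 7 embryos was pooled per genotype, cut with the most recent somite border as the guide, and hybridised in a dye swap. Both arrays were treated as 1 comparison of 2 pools, since the labels describe no separate pools for the swap; whether the same extracts were labelled again is not stated.

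The deposited files are scanner output with a spot per row. The deposited intensity values are mean pixel brightness per spot in Cy3 and Cy5 and the median of the local background, neither corrected nor normalized, per the file headers. The deposited log10 ratio is Cy5 over Cy3 after the scanner software's spatial background detrending and LOWESS dye normalization, per the file headers. The deposited p-value is the software's own error model for a spot within an array, per the file headers, and covers technical error only. The submitters' processing notes name Agilent Feature Extraction 9.5.3, while the file headers give version 7.5.1. The header's grid of 206 rows and 430 columns and the array format that the series text names were not reconciled. Background that is subtracted too strongly inflates ratios of dim genes, and an offset shrinks them.

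From these values, mean signals were background-corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, fitted on all 43430 spots. Each array was normalized by loess within the array, with control spots at weight 0. Ratios were turned to mutant over wildtype from the dyes in the labels. Spots with a non-uniformity flag were left out (205 on replicate 1 and 90 on replicate 2) and saturated spots were kept. Spots of a probe were averaged to 41013 probes, and the detected probe with the highest mean log2 intensity stood for a gene. Detected means well above background, by the software's flag, in at least 1 genotype on both arrays. A gene was counted when its log2 ratio reached log2 of 1.5 in the same direction on each array. Where a genotype was not well above background on either array, a bound was given. It sets the bright pool's mean over arrays against, per array, the higher of the lowest signal among probes well above background and the probe's own, per channel after loess and Aquantile normalization.

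Median Cy3 and Cy5 signals were 150 and 159 on replicate 1 and 146 and 155 on replicate 2, against 109 and 91.3, and 113 and 92.2, at the negative control spots. Cy5 was saturated at 117 and 122 gene spots and Cy3 at 18 and 9. Over 7 probes printed many times, the within-array SD of the log2 ratio was 0.16 on replicate 1 and 0.23 on replicate 2. The E1A spike-in spots had medians of 120 and 107 on replicate 1, close to the negative controls, and were not used.

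Gene names were updated through the accessions in the files and a RefSeq table of GRCm38.p6, used for names only. Of the probes, 19435 were named by accession, 3620 by a current symbol and 2899 by a synonym on the same chromosome; 544 matched several genes and were given no name, and 14515 kept the files' name. Among 25579 named probes with a chromosome, 523 lay on another chromosome in the table, among the genes past the size rule only Fdps, which the files place on chromosome 10 and the table on chromosome 3. Xist is listed in the files under another name. Members of the lists with no matching probe, such as Hoxb8, Hoxd3, Kdm5d and Tsix, were not analysed here. Values of some single genes are not reported here.

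The 34 gene lists, with 481 entries, the size rule and the alternatives were fixed before the data were examined; 3 lists in the closing section were added after the calls were seen. For each list the median log2 ratio of detected members was set among 10000 random lists of the same size drawn within 20 intensity bins, as a description of these arrays. Of the 34 lists, 14 had a percentile below 2.5 or above 97.5, against 6 of 100 random lists in the simulation below. The random lists were drawn gene by gene from all detected genes and do not allow for genes that vary together. An extreme percentile alone is therefore not read as a pathway change. Genes named were Cdx1, Cdx2 and Cdx4; the 12 highest and 12 lowest past the size rule by the smaller of the arrays' absolute ratios, leaving out clone-like names; from each list up to 4 members past the rule, 6 for Hox lists, or the largest absolute ratios to make 2; every measured Y-linked and X inactivation gene; and members of any count of 5 or fewer. A few members of the lists were named in addition after their values were seen: Hoxb13, Hoxc10, Hoxd13, Aldh1a2, Pax3, Tbx6, Msgn1, Hes7, Fgf8 and Wnt3a. So were genes past the size rule outside the lists: Wnt2, Rnf43, Fzd7, Gdf10, Tgfb2, Inhba, Foxc1, Mesp1, Rgma and Q80yz1. A permutation p planned for the Hox correlation is not printed, because genes are not replicates of a genotype.

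The steps were tested on simulated data: dye-swapped arrays built from the real spots of this comparison, run on 26098 genes with 50 changed genes per fold. Of these, 1 was called at 1.3-fold, 6 at 1.5-fold, 44 at 2-fold and 50 at 4-fold, none in the wrong direction. The median recovered fold was 1.86 for 2-fold and 3.36 for 4-fold, and none of 25898 unchanged genes was called. Of 100 random lists, 6 had a percentile below 2.5 or above 97.5. In this simulation the rule missed most changes of 1.5-fold and the recovered folds were below those put in. Its noise was normal with the SD pooled over genes, its dye term per probe was normal, and the dimmest genes were not among those changed. Its lack of false calls holds for such noise only, while on the real arrays 91 genes followed the dye past the same thresholds.

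Alternatives were no background subtraction, an offset of 16, the scanner software's ratio, median centring, Aquantile normalization after loess, no detection filter, detection in both channels, the median over probes, flagged spots kept, and each array alone. For the counts they also included 2-fold and 1.3-fold thresholds, the software's p-value under 0.01 on each array, and the mean of both arrays.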

Results

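Posterior tissue of mouse embryos at the 13-somite stage was profiled on a pair of dual-colour oligonucleotide arrays. RNA pooled from 7 embryos heterozygous for Cdx2 and lacking Cdx4 was set against RNA pooled from 7 wildtype embryos, and the dyes were exchanged between the arrays. Replicate 1 carried the mutant pool in Cy5 and replicate 2 carried it in Cy3. The design was read as 1 pool per genotype, since the labels describe no separate pools, with the arrays as the same comparison in both dye orientations. A difference between the pools has no biological replicate check, no p-value between genotypes is given, and the errors below are the SD of the 2 arrays, which is technical. Of the 41174 gene spots, 79.8% in Cy3 and 82.5% in Cy5 were well above background on replicate 1, and 77.4% and 80.6% on replicate 2. Of the genes on the array, 26098 were well above background in at least 1 genotype on both arrays. The number of arrays limits the precision.

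The comparison asked which transcripts differ in the posterior embryo when Cdx function is reduced. Cdx4, the gene absent from the mutant, was 5.75-fold lower in the mutant pool, with a log2 ratio of -2.52 ± 0.12 (SD of 2 arrays). Its probe lies at X:94733554-94733613 in the files' coordinates, whose genome build they do not name, and it remained well above background in the mutant channel of both arrays. Cdx2, of which the mutant keeps 1 intact copy, had a log2 ratio of -0.05 ± 0.09, smaller than its own spread between arrays. The chosen Cdx2 probe spans 144626911 to 144628057 on chromosome 5, and a dimmer Cdx2 probe gave 0.00. Where these probes lie relative to the altered parts of the alleles is not given in the sources used here, so the Cdx2 value does not check the genotype. Cdx1, the remaining family member, had a log2 ratio of 0.19 ± 0.09 and did not pass the size rule.

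In total, 55 genes were higher and 60 were lower in the mutant pool by at least 1.5-fold on each array, together 0.441% of the genes detected. At 2-fold on each array the counts were 20 and 7. Among the largest increases with the processing used here were Meox1 (4.34-fold, log2 ratio 2.12 ± 0.02), a somite transcription factor, and Ripply2 (4.30-fold), a repressor at the forming somite boundary. Tcf15 (4.06-fold), a basic helix-loop-helix factor of the paraxial mesoderm, and Pcdh8 (3.96-fold), a protocadherin of the anterior presomitic mesoderm, were also among them. The other genes at the top of the increase were Arg1 (3.73-fold), Nepn (3.65-fold), Trh (3.95-fold with a log2 SD of 0.53), Ptn (2.86-fold), Ism1 (2.67-fold), Foxc2 (2.56-fold) and Fst (2.34-fold). Cer1, a secreted antagonist of Nodal and BMP, was 3.44-fold higher, and its wildtype signal was well above background on 1 of the arrays.

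**Figure D1:**
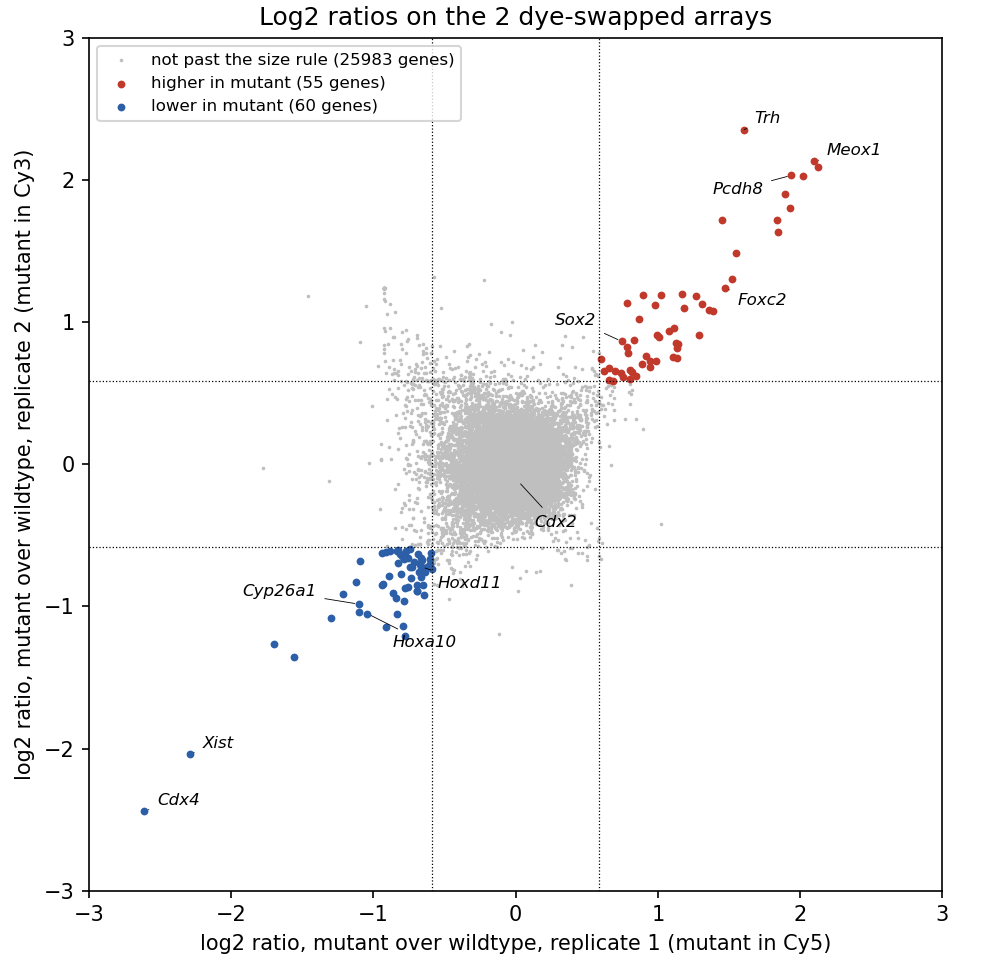
Each point is 1 of 26098 detected genes, with its log2 ratio of mutant over wildtype on replicate 1 (x axis) and on replicate 2 (y axis); dotted lines mark 1.5-fold. The 55 genes higher (red) and 60 lower (blue) lie along the diagonal from Cdx4 at -2.52 to Meox1 at 2.12, and Cdx2 lies in the central cloud.

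Xist, the RNA that coats the inactive X chromosome, was lower besides Cdx4. Its mutant signal was not well above background on either array, so only a bound is given and Xist cannot be ranked against Cdx4. With the processing used here, Xist was at least 3.95-fold lower in the mutant pool. Coro2a was 2.79-fold lower (log2 ratio -1.48 ± 0.31), and the serum amyloid genes Saa3 and Saa1 were 2.74-fold and 2.28-fold lower. Ankrd1 (2.10-fold), Cldn5, a tight junction protein of endothelium (2.09-fold), Hoxa10 (2.07-fold), Cyp26a1 (2.06-fold), Plac1 (2.04-fold), Msmo1 (1.86-fold) and the copper transporter gene Atp7a (1.84-fold) completed the set. Of the 32 genes past the size rule with more than 1 detected probe, 29 had probes whose mean log2 ratios all had the same sign. For several of them another probe was near 0, so a shared sign is weak agreement. The second Rgma probe had -0.12 on replicate 1 and 0.15 on replicate 2. The second Q80yz1 probe had a mean of 0.02 against 1.14, at nearly the same brightness. The Fst probe used gave 1.23 on the log2 scale and its dimmer probe 0.38, and the Cyp26a1 probes gave -1.04 and -0.84.

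As a measure of dye effects, 91 genes would have passed the same thresholds had the second array not been turned, 89 of them brighter in Cy3, and 2 at 2-fold. Of the 91, 38 had a mean log2 intensity above 15, against 0 of the genes past the size rule. Most of the others were dim, with a mean log2 intensity between 6.36 and 7.02. Hoxd11 (6.71), past the size rule, lay in that dim range, and Cer1 (7.09) and Pcdh8 (7.17) lay just above it. The genes brighter in Cy5 numbered 2, and they carried clone names. Over all detected genes the arrays' log2 ratios had a Pearson r of 0.067, and the SD between arrays pooled over genes was 0.19. The counts depend on processing. Median centring in place of loess left 27 higher and 16 lower, so that 62.8% of calls were higher against 47.8%, and the scanner software's own ratios gave 167 and 190. Median centring ended the calls of Hoxa10, Plac1, Atp7a, Msmo1, Dusp4, Dll1, Greb1, Sox2, Sox18 and Slc2a1, whose mean ratios each moved by less than that pooled SD of 0.19. Sizes of dim genes also depend on it: with the software's ratios, Meox1 had a log2 ratio of 2.98 and Pcdh8 of 4.05.

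Hox genes, which give positional identity along the axis, were read by paralog group, and differences between the groups were not tested. Of 7 detected posterior Hox genes, in paralog groups 10 to 13, Hoxa10 fell (log2 ratio -1.05 ± 0.01) and Hoxd11 fell (1.62-fold, -0.69 ± 0.04), and the other 5 did not pass the size rule. The call of Hoxa10 ended with median centring and that of Hoxd11 without background subtraction (log2 ratio -0.48). Their median was -0.43, below all 10000 random lists of the same size and intensity, and 6 of the 7 lay below 0 on both arrays; it was -0.27 with replicate 1 left out and -0.75 with the software's ratio. Hoxd13 had -0.81 on replicate 1 and -0.33 on replicate 2, Hoxc10 had -0.45 and -0.42, and Hoxb13 lay at 0.04. Without a detection filter, which admits dim members, the median of the group was -0.10. None of the 13 detected trunk Hox genes passed the size rule. Their median was 0.00, but -0.081 on replicate 1 and -0.093 on replicate 2, and 6 lay below 0 on both arrays against 2 above. None of the 9 anterior genes passed (median 0.01, and 0.14 with replicate 1 left out). Hoxc6 at -0.51 ± 0.19, past the threshold on replicate 1 alone, and Hoxa7 at -0.31 ± 0.14 were the farthest in the trunk groups, and Hoxb1 at 0.52 ± 0.03 and Hoxc4 at -0.35 ± 0.17 in the anterior groups. Across the 29 detected Hox genes, paralog group number and log2 ratio had a Pearson r of -0.44 and a Spearman rho of -0.39. This is a correlation across genes, which are not independent replicates. Hoxa13, Hoxb13 and Hoxd13 are equally far from the median group; leaving out 2 of these 3 gave an r from -0.54 to -0.41, and leaving out all 3 gave -0.49. The ParaHox and even-skipped genes did not pass (5 detected, median -0.03), with Pdx1 at -0.12 ± 0.19 and Evx1 at -0.05 ± 0.06.

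**Figure D2:**
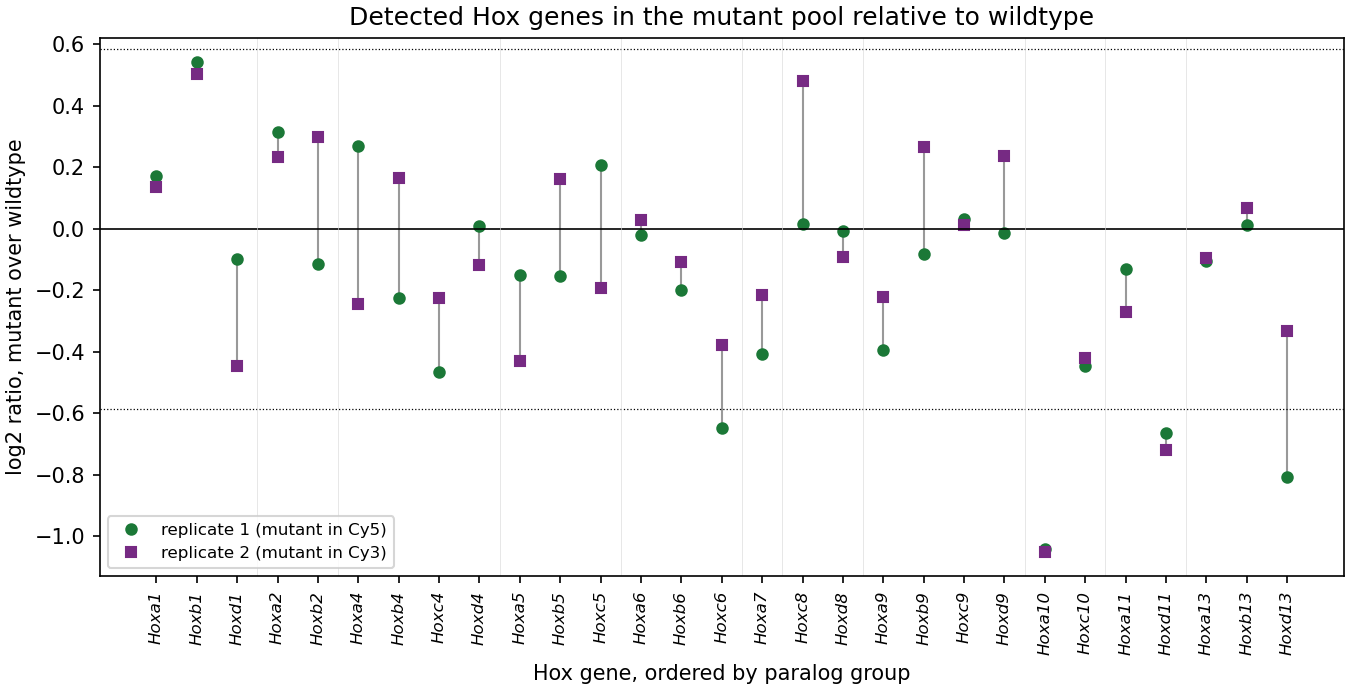
Log2 ratio of mutant over wildtype (y axis) for each of the 29 detected Hox genes, ordered by paralog group (x axis), on replicate 1 (circles) and replicate 2 (squares); grey bars join the arrays and dotted lines mark 1.5-fold. Hoxa10 near -1.05 and Hoxd11 near -0.69 lie past the lower line on both arrays.

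Genes of segmentation and the paraxial mesoderm were among the largest increases with the processing used here. In the list for somites and their derivatives, 3 of 9 detected members rose, Meox1, Tcf15 and Foxc2, and the other 6 did not pass, among them Pax3 at 0.02 ± 0.04 and Aldh1a2 at 0.30 ± 0.10. The list median was 0.13, above 99.9% of random lists, but 0.084 without background subtraction, 0.074 without a detection filter and 0.21 with replicate 2 left out. In the presomitic mesoderm list, 2 of 10 rose, Pcdh8 and the Notch ligand Dll1 (1.59-fold, 0.67 ± 0.02), while Tbx6 at 0.06 ± 0.16 and Msgn1 at -0.12 ± 0.03 did not pass. Its median of 0.07 turned to -0.02 on replicate 1 alone and was 0.18 on replicate 2 alone. Ripply2 and Dll1 were the 2 of 15 members of the Notch and segmentation clock list that rose (median 0.12, and 0.20 with replicate 1 left out), and the clock gene Hes7 was at 0.02 ± 0.23.

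In the retinoic acid, FGF, Wnt and BMP lists, Cyp26a1 and Dusp4 fell and no gene rose. Cyp26a1, which clears retinoic acid from the tailbud, was the only one of 13 detected retinoic acid genes to pass the rule (median 0.05); the retinol transporter Stra6 was at 0.54 ± 0.04. Of 19 FGF pathway genes, Dusp4, a phosphatase induced by FGF signalling, fell (1.79-fold, -0.84 ± 0.07). The FGF median was 0.16, above all random lists, but 0.085 with median centring and 0.25 with the software's ratio, with Fgf18 at 0.57 ± 0.14 and Fgf8 at 0.10 ± 0.11. None of the 25 genes in the Wnt list passed. Their median was 0.10 (1.07-fold), above all random lists, but 0.045 on replicate 1 alone, and 0.16 with the software's ratio. Nkd1 was at 0.58 ± 0.12, Wnt5a at -0.51 ± 0.11 and Wnt3a, the tailbud ligand, at -0.46 ± 0.05. Wnt genes outside the list passed in both directions: Wnt2 (1.75-fold) and Rnf43 (1.66-fold) were lower and Fzd7 (1.54-fold) was higher. Among 13 genes of the primitive streak and tailbud progenitors, Fst rose, Cyp26a1 and Greb1 fell (Greb1 1.73-fold) and 10 did not pass, with a median of 0.00. Brachyury (T), a member of that list and of the notochord and floor plate list, had -0.49 ± 0.03 and did not pass. Foxa2, in the notochord and floor plate list, had 0.33 ± 0.10. None of the 7 detected members of the notochord and floor plate list passed. Its median was 0.03, but -0.033 on replicate 1 alone and -0.025 on replicate 2 alone. None of the 16 detected genes in the BMP and TGF-beta list passed (median -0.02), with Msx1 at -0.30 ± 0.15 and Id3 at 0.29 ± 0.13. Outside that list, Gdf10 (1.93-fold) and Tgfb2 (1.56-fold) were higher and Inhba (1.77-fold) was lower, all past the rule.

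**Figure D3:**
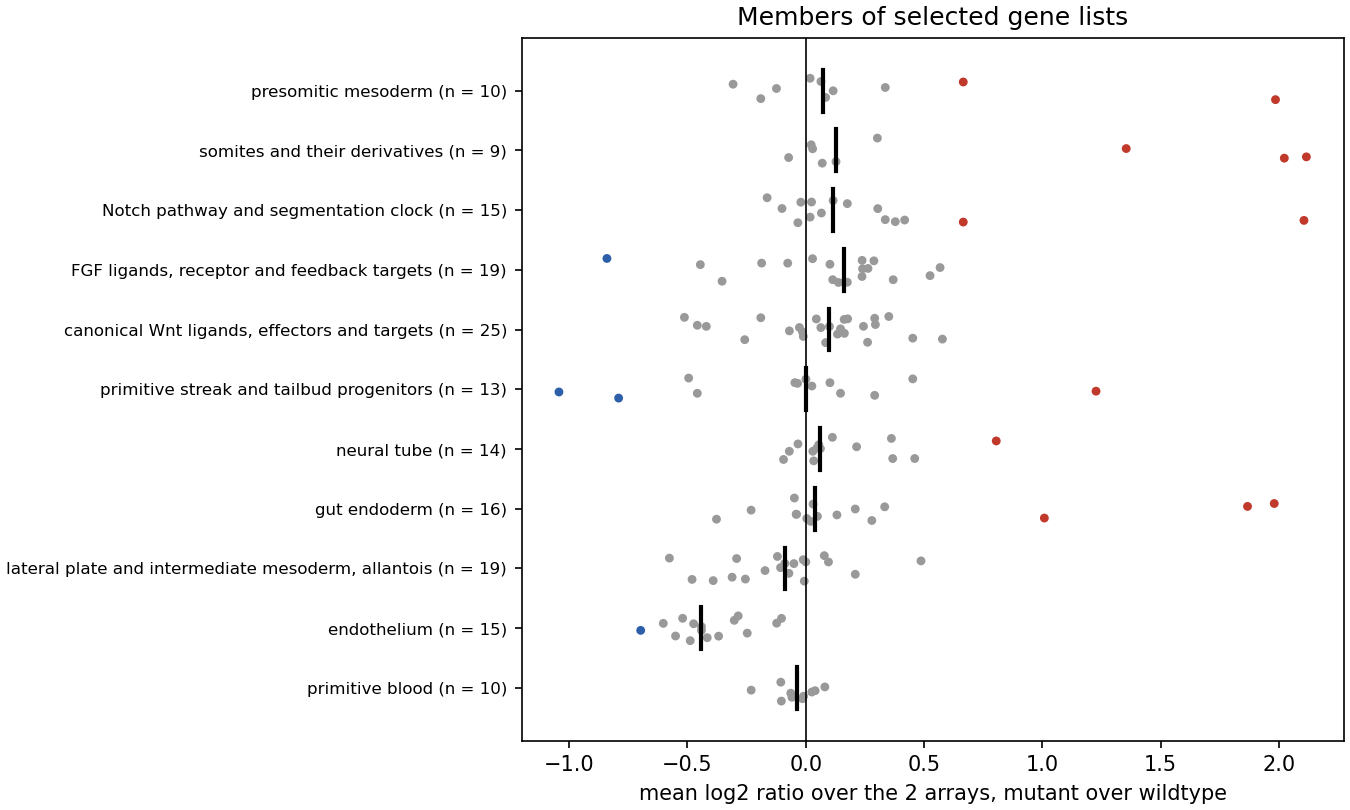
Mean log2 ratio of mutant over wildtype (x axis) for the detected members of 11 gene lists (rows); black bars are list medians, red and blue points are genes past the size rule. The 15 endothelial genes lie below 0 with a median of -0.44 (with median centring, 9 of 15 are below 0 on both arrays), and the largest increases lie in the presomitic, somite, Notch and gut lists.

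Markers of other tissues in the dissected region were read in the same way. Of 15 detected endothelial genes, all lay below 0 on both arrays with a median of -0.44, below all random lists. With median centring 9 of the 15 lay below 0 on both arrays, at a median of -0.45. Sox18, a transcription factor of vessel formation, fell (1.62-fold, -0.70 ± 0.08), and the other 14, including the receptor gene Kdr at -0.60 ± 0.33, did not pass. The call of Sox18 also ended without background subtraction. Primitive blood genes did not pass (10 detected, median -0.04, but 0.053 on replicate 1 alone), with Alas2 at -0.23 ± 0.09 and Klf1 at -0.11 ± 0.13. In the gut endoderm list Nepn, Trh and Spink1 (2.01-fold) rose, 13 others did not pass and the median was 0.04, and 0.14 with replicate 1 left out. Sox2, a transcription factor of neural progenitors, was the 1 of 14 neural tube genes that rose (1.75-fold, 0.81 ± 0.08; list median 0.06, and 0.17 with replicate 1 left out), with Irx3 at 0.46 ± 0.25. None of 19 lateral plate, intermediate mesoderm and allantois genes passed (median -0.09, above 0.33% of random lists), with Foxf2 at -0.58 ± 0.26 and Lhx1 at 0.49 ± 0.73. None of 8 surface ectoderm genes passed (median 0.17, above all random lists, and 0.28 with the software's ratio), with Wnt6 at 0.53 ± 0.02 and Trp63 at 0.26 ± 0.03.

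The remaining lists held 1 gene past the size rule among them, apart from Xist in the X inactivation list. The glucose transporter gene Slc2a1 rose (1.90-fold, 0.93 ± 0.25) in the hypoxia list of 13 detected genes (median -0.04), where Ndrg1 was at 0.34 ± 0.05. Visceral endoderm and yolk sac genes had a median of 0.01 with Amn at 0.42 ± 0.07 and Rbp4 at 0.31 ± 0.37. Neural crest genes had 0.05 with Ets1 at -0.56 ± 0.07 and Tfap2b at 0.15 ± 0.00, and heart genes had -0.01 with Myl7 at 0.11 ± 0.02 and Nkx2-5 at -0.09 ± 0.08. Forebrain and head genes had -0.02 with Lhx2 at -0.28 ± 0.76 and Emx2 at 0.28 ± 0.19, and germ cell genes had 0.02 with Kit at -0.40 ± 0.03 and Dppa3 at 0.26 ± 0.03. The p53 targets had -0.07, and -0.033 without background subtraction, with Btg2 at -0.35 ± 0.03 and Zmat3 at 0.22 ± 0.06, and the immediate early and heat shock genes had -0.07, and -0.15 with the software's ratio, with Atf3 at -0.61 ± 0.08 and Hspa1a at -0.36 ± 0.30. Cell cycle genes had 0.03 with Ccne1 at 0.26 ± 0.06 and Cdc20 at 0.22 ± 0.09. Of 21 ribosomal protein genes, 12 were saturated in Cy5 on both arrays, so their ratios are not measurements of a difference; Rplp1 was saturated in both channels and has no ratio here. The list had 0.01, with -0.37 on replicate 1 and 0.49 on replicate 2, and Rps16, which was not saturated, had -0.18 ± 0.13.

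Of the 4 detected Y-linked genes, 3 were above 0 on both arrays, opposite in sign to Xist. Ddx3y had a log2 ratio of 0.58 ± 0.16, Uty 0.50 ± 0.27 and Eif2s3y 0.39 ± 0.37, short of the size rule, and Usp9y had -0.07 ± 0.06. The median of the 4 was 0.45, and 0.38 with median centring, where none of the 3 was above 0 on both arrays. It was 0.67 on replicate 1, where the 3 genes reached the threshold, and 0.22 on replicate 2, where none did. None of the listed genes flanking the altered loci passed. Xist, which also lies near Cdx4, and Atp7a (1.84-fold lower), farther along the X chromosome, were not in that list. The 12 detected neighbours of Cdx4 on the X chromosome had a median of 0.01, with Hdac8 at -0.27 ± 0.08 and Tsx at 0.20 ± 0.03, and the 18 neighbours of Cdx2 on chromosome 5 had -0.02, with Rasl11a at 0.46 ± 0.10 and Slc46a3 at -0.45 ± 0.09. X-linked genes made up 9.09% of the genes past the size rule that have a chromosome in the files and 3.40% of those detected. Of these, 7 were lower, including Cdx4 and Xist, and those higher included Pcdh19 and Lhfpl1.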

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

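No paired analysis was possible because each array already sets the mutant pool against the wildtype pool, and 1 pool per genotype allows no test. The mean log2 ratio of all 115 genes past the size rule kept its sign under each alternative that used both arrays and measured them. This is a weak check. Only the sign of the mean was compared, genes this far from 0 seldom change it, and Aquantile normalization changed none of the calls. Single arrays are no check of the sign, since the rule already requires the same direction on each array. On replicate 2 alone 1 gene changed sign, because the probe for each gene was chosen again and another probe stood for it. Of the 115 genes, 81 were still past the rule without background subtraction, 40 with median centring, 95 with the median over probes and 115 with the software's ratio. The cause of the changes below was not tested. Signal over background limits dim genes, whose ratios grow as the offset falls.

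Against 55 higher and 60 lower, higher and lower counts were 43 and 38 without background subtraction, 80 and 91 with an offset of 16, 78 and 95 by the mean of both arrays, 167 and 190 with the software's ratio, 27 and 16 with median centring, 20 and 7 at 2-fold, 140 and 196 at 1.3-fold, and 84 and 107 by the software's error model. On single arrays, where dye effects are not removed, they ranged from 93 to 321 higher and from 128 to 467 lower. The count of dye-following genes, 91, was 50 without background subtraction, 233 with an offset of 16, 510 with the software's ratio and 1098 with median centring.

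The Cdx4 log2 ratio of -2.52 was -2.23 without background subtraction, -2.85 with an offset of 16 and -3.16 with the software's ratio, and ranged from -2.61 to -2.44 on single arrays. Cdx2 ranged from -0.12 to 0.02 on single arrays. The Spearman rho of Hox paralog group and log2 ratio, -0.39, was -0.53 with the software's ratio and -0.30 without a detection filter, and ranged from -0.42 to -0.30 on single arrays.

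Without background subtraction, list medians were 0.12 for FGF, 0.084 for somites, 0.12 for surface ectoderm, -1.60 for X inactivation and -0.37 for sterol genes. With an offset of 16 they were -0.53 for posterior Hox, 0.18 for Notch, 0.19 for somites, 0.22 for surface ectoderm, -3.14 for X inactivation and -0.48 for sterol genes. With the software's ratio they were -0.75 for posterior Hox, 0.16 for Wnt, 0.25 for FGF, 0.18 for Notch, 0.20 for somites, 0.19 for neural tube, -0.58 for endothelium, 0.28 for surface ectoderm, -0.15 for immediate early genes, -4.76 for X inactivation, -0.39 for the second endothelial list and -0.50 for sterol genes. Median centring gave 0.085 for FGF and -0.48 for sterol genes, no detection filter -0.10 for posterior Hox and 0.074 for somites, and the median over probes -0.34 for sterol genes. On single arrays they ranged from -0.45 to -0.27 for posterior Hox, 0.045 to 0.082 for Wnt, 0.15 to 0.20 for Notch, 0.18 to 0.21 for somites, 0.050 to 0.17 for neural tube, -0.37 to -0.36 for endothelium and -0.38 to -0.33 for sterol genes. The X inactivation values are those of Xist alone, whose mutant signal was not well above background, so they are not measured sizes and their order against Cdx4 is open. The presomitic mesoderm median was -0.019 on replicate 1 alone and 0.18 on replicate 2 alone.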

Other observations

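The tests of the dye effect, of somite tissue, of background correction, of the sex ratio and of the region around Cdx4 were chosen after the results were seen; the second endothelial list and the sterol and actin lists were written after the genes past the size rule were known but before their own values were. Among genes of sterol synthesis and uptake, Msmo1 (1.86-fold) and Fdps (1.65-fold) were the 2 of 22 detected members past the size rule, and the Fdps probe lies on another chromosome than the gene in the RefSeq table, so that it may read a related copy. Without these genes the median log2 ratio of the other 20 was -0.39, and 18 lay below 0 on both arrays, with Idi1 at 0.03. The hypothesis that sterol genes were lower together held in this test, over 1 pool per genotype.

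Actin cytoskeleton targets of SRF and YAP gave a weaker pattern. Ankrd1 (2.10-fold), Actg2 (1.85-fold), Cnn1 and Lima1 (each 1.61-fold) fell. The median of the other 17 detected members was -0.20, at the edge of the bound of -0.2 set for the hypothesis of a group decrease, and 11 of them lay below 0 on both arrays, so the test passed only narrowly. With median centring Fdps, Actg2, Cnn1 and Lima1 were no longer past the size rule, nor were Fdps and Actg2 with the median over probes, or Cnn1 without background subtraction.

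The 15 detected endothelial genes lay below 0 on both arrays, 1 of them past the size rule. A dye effect is argued against, since 100% of the 15 listed genes lay below 0 in both dye orientations after loess. With median centring, which leaves the intensity-dependent dye trend in, 9 of 15 did, while the median over arrays was -0.45. A second endothelial list, with no member past the size rule, had a median of -0.26 over 24 genes, 19 of them below 0 on both arrays, which is consistent with fewer endothelial cells in the mutant pool. Lower expression per cell, and a difference in dissection between pools, were not tested and stay open.

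Meox1, Tcf15, Foxc2, Ripply2 and Pcdh8 were higher in the mutant pool, while most other members of the somite and presomitic lists did not pass the size rule. Outside those lists, Foxc1 (2.27-fold) and Mesp1 (1.63-fold) were also higher past the rule. The test of background correction and normalization covers Meox1, Tcf15, Foxc2, Ripply2 and Pcdh8 only. They were picked from the largest increases in the same data, so they were likely to stay past the threshold. No conclusion on processing as a cause is drawn from it. The smallest log2 ratio of these 5 genes over both arrays and all processing alternatives was 0.80, above the threshold of 0.58. Dll1, another member past the size rule, lost its call with median centring. More somite tissue in the mutant dissection cannot be told apart from a change in expression. The somite list had a median of 0.13 over 9 detected genes, but 3 of them lay under 2-fold over the negative controls and Pax3 is also a neural gene, and Pax1, Uncx, Myf5 and Myog were not detected. The genotype itself stays among the open explanations.

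Xist was lower in the mutant pool, by at least 3.95-fold with the processing used here (log2 ratio -1.60 without background subtraction). A regional change around Cdx4, whose locus lies near Xist, is argued against by a median of 0.0054 over 12 listed neighbours, for these genes as a set. Single linked genes outside that list are not covered. Atp7a, at X:97529065 against X:94733554 for Cdx4 in the files' coordinates, was 1.84-fold lower. The Y-linked genes Ddx3y, Uty and Eif2s3y had a median of 0.50 and were higher on both arrays after loess. The test left out Usp9y, a dim Y-linked gene (mean log2 intensity 6.33) at -0.07. With Usp9y included, the list median was 0.67 on replicate 1 and 0.22 on replicate 2. The values of the 3 genes after loess go with more male embryos in the mutant pool. With median centring none of the 3 was higher on both arrays. The sex of the embryos is not given in the labels, and other genes that differ between the sexes may share this difference between the pools.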
